A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

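Ribo-Zero Gold depleted total RNA of 6 yeast samples was sequenced as TruSeq stranded libraries, per the labels. The deposited files hold raw counts per open reading frame (column 3), with no header, and a second column of lengths that equals the coding length of the reference in codons minus 10 for 5969 of 6007 open reading frames. Per the submitters' processing notes CASAVA 1.8, Bowtie2 2.3.4.2, TopHat2 2.0.9 and the sacCer3 build were used, listed with no role or order. The counter, the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. The files hold 6696 open reading frames, of which 6008 are in the reference annotation (R64) and 688 are not. The latter took 0.206% to 0.624% of the counts and were kept. In 1 file the line ends were of the Windows kind, which does not touch the values.

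PAU1 and PAU14, which are near-identical, had equal counts in each library. Shared reads therefore seem to have been counted in each copy or split evenly, which was not tested. In all 305 open reading frames lie in families of near-identical copies (BLAST 2.17.0, at least 95% identity over 80% of the length), and their members are named as uncertain. Genes with FLO, PAU, HXT, MAL, IMA, COS, ENA, MPH, TDH and ribosomal protein names were treated so as well, whether or not they met these limits. The TEF1 to TEF2 count ratio was 0.798 in deletion glucose replicate 1 and 0.997 to 1.02 in the other libraries, and the EFT1 to EFT2 ratio 0.851 and 0.991 to 0.997. A further 8 open reading frames lie inside another on the opposite strand.

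Counts were tested with edgeR 4.0.16 in R 4.3.3. After filterByExpr with its defaults (550 open reading frames left out, 6146 tested) and TMM scaling (factors 0.990, 1.02, 0.990, 1.07, 1.08 and 0.868, in the order of the depths below), a model with 1 mean per group was fitted to the 6 libraries. It has 2 residual degrees of freedom, both from the glucose pairs, 86.7 prior degrees of freedom and a common biological coefficient of variation of 5.54%. Each mannose group is 1 library, assumed to vary like the glucose libraries. The pairs vary more than counting error alone (chi-square per degree of freedom 12.0 in wild type and 24.4 in the deletion). Genes were called at an adjusted p under 0.05 (quasi-likelihood F test, Benjamini-Hochberg adjustment over the genes tested). Standard errors are the absolute log2 fold change over the square root of F. The comparisons were genotype in glucose, mannose in each genotype, genotype in mannose, and the interaction. Group means and SDs in CPM are TMM-scaled.

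Samples, the tests of the comparisons and of the lists, gene lists, the named-gene rule and all but 4 alternatives were fixed before the data were examined. The 10 tests of explanations were chosen later, 4 of them, and the paired intervals in 2 others, only after their results were seen. Of 39 lists 37 were tested as sets by camera (limma 3.58.1, correlation 0.01) on log2 CPM with a prior count of 2. Camera at an estimated correlation and fry were companions. At an estimated correlation camera has only the 2 residual degrees of freedom of the fit, which leaves it little power. LEU2, MET17, URA3, ATP8, MF(ALPHA)2 and SPS2 are list members that were not tested, since they did not pass the filter. Named by rule were CYC8, TUP1 and the auxotrophic markers, then called genes with a standard symbol and at least 10 CPM in the higher group: the 10 largest rises and falls in glucose (both replicates on the same side), and 5 of each in the other comparisons. In each list the 2 largest rises and falls could be named, and any member of a list of 8 or fewer. For genotype in mannose, in an addition to the fixed tests, a list's median was ranked among 10000 random lists matched on expression. Overlaps of calls were set beside those of independent lists and, for comparisons with shared controls, simulated unchanged groups.

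Depth was 37954565 and 44084216 counts (wild type, glucose), 39015900 (wild type, mannose), 30702206 and 39266407 (deletion, glucose) and 26195734 (deletion, mannose). A count of 0 allows up to 3 counts, or 0.0790, 0.0681, 0.0769, 0.0977, 0.0764 and 0.115 CPM, a limit that covers counting error only. The 10 most abundant genes took 18.8%, 18.5%, 20.5%, 18.1%, 18.0% and 12.4% of the counts. Tested on simulated data with the fitted spread, with 50 genes changed at each fold, the test recovered 48%, 86%, 92% and 92% of genes changed 1.25, 1.5, 2 and 4-fold for 2 against 2 libraries (2 false of 161 calls), 32%, 82%, 88% and 90% for 1 against 2 (5 of 151) and 16%, 82%, 88% and 98% for 1 against 1 (10 of 152). Of 20 simulated lists with 12 of 15 members raised camera called 20, and 0 of 20 unchanged lists. Simulated genes were independent, while the tested lists had estimated correlations of up to 0.61, so false calls in correlated lists are not covered. The simulated mannose libraries were given the fitted spread, so the simulation does not test whether they vary like the glucose libraries. Each simulated gene had the spread of the fitted trend and none of its own. Few genes were changed, in both directions, while 67.9% of genes were called for genotype in glucose in the data. Errors of scaling where most genes differ are therefore not covered by the simulated false calls.

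The alternatives were DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, no filter and a stricter one, a threshold of 1 on the log2 fold change, leaving out each library, the glucose libraries alone, a replicate block, an additive model, and the set test companions. Chosen after seeing the data were a crossed block, a fixed biological coefficient of variation of 0.2, families of near-identical copies merged, and fold changes without smooth trends on GC content and coding length (loess, span 0.5, nuclear open reading frames of the reference only). Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.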

Results

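Stranded RNA sequencing of total RNA, depleted of ribosomal RNA, was made from Saccharomyces cerevisiae BY4741 and from a strain of the same background lacking CYC8. CYC8 encodes a corepressor that acts with Tup1 to keep many genes silent. Per the labels, cells were grown in rich medium (1% yeast extract, 2% peptone) with 2% glucose, or with 2% mannose for 3 h to produce free O-glycans. The time in glucose medium is not given in the sources used here. The 6 libraries form 4 groups: wild type in glucose (2), wild type in mannose (1), the cyc8 deletion in glucose (2) and the deletion in mannose (1). The labels do not say whether the replicates are separate cultures. The libraries hold 26195734 to 44084216 counts, the fewest in the deletion in mannose. Values below are CPM scaled by TMM factors, and changes are log2 fold changes ± standard error. A mannose group is 1 library, so its values have no replicate error, and its tests borrow the spread of the glucose pairs.

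CYC8 (YBR112C, chromosome II, 462870 to 465770, 1 coding exon, reference R64, the sacCer3 build) stood at 203 ± 4.97 CPM (SD, n = 2) in wild type in glucose and 2.55 ± 0.531 CPM (SD, n = 2) in the deletion. In mannose it stood at 197 CPM in wild type and 7.92 CPM in the deletion. The deletion libraries therefore still held 71, 124 and 180 CYC8 counts. Its log2 change in the deletion was −6.30 ± 0.11 in glucose (adjusted p = 2.25e-70) and −4.63 ± 0.14 in mannose (adjusted p = 2.48e-50, both from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). TUP1, the partner of CYC8, fell less, at −0.51 ± 0.08 in glucose and −0.79 ± 0.11 in mannose, the latter at −1.59 without trends on GC content and coding length. Of the auxotrophic markers of the strain, LEU2, MET17 and URA3 had 0 counts in each of the 6 libraries, which allows at most 0.0681 to 0.115 CPM by counting error alone. HIS3 held 583 to 2151 counts per library, and it stood at −0.48 ± 0.08 in the deletion in glucose.

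Across 6146 tested open reading frames, replicates had Pearson correlations of log2 CPM of 0.997 (wild type) and 0.996 (deletion) in glucose. These are correlations across genes, which are not independent replicates. The first principal component held 78.0% of the variance and ordered the libraries from wild type in glucose (−58.1 and −57.9) and in mannose (−43.9) to the deletion in glucose (34.9 and 35.8) and in mannose (89.2).

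**Figure D1:**
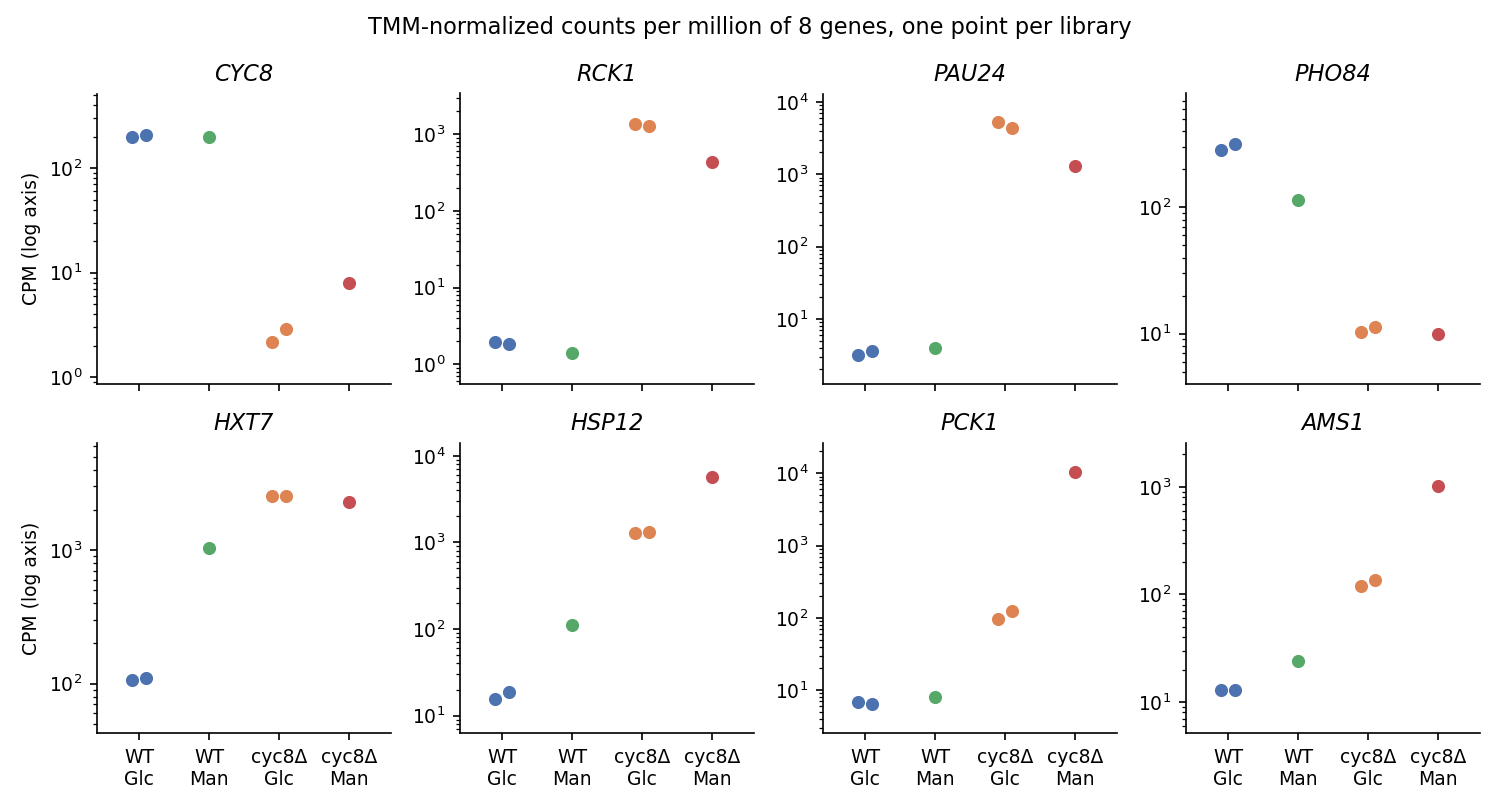
TMM-scaled CPM (log axis) of 8 genes, with 1 point per library in the 4 groups (WT, wild type; cyc8Δ, deletion; Glc, glucose; Man, mannose). CYC8 is low in the 3 deletion libraries, and PCK1 stands at 10509 CPM in the deletion in mannose against 8.08 CPM in wild type in mannose.

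The first comparison asks which transcripts differ without the corepressor in glucose, 2 libraries against 2. The largest rises were in seripauperins, small cell wall glycoproteins of anaerobic growth. PAU24 went from 3.36 ± 0.278 to 4814 ± 589.7 CPM (SD, n = 2 each), a change of 10.48 ± 0.14. PAU1 and PAU14, which had equal counts in each library, each rose by 10.04 ± 0.13. The kinase gene RCK1, which has no near-identical copy, went from 1.91 ± 0.0523 to 1322 ± 46.7 CPM (SD, n = 2 each), a rise of 9.44 ± 0.12 (adjusted p = 6.03e-79, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among the largest falls besides CYC8 were ARO10 (−5.38 ± 0.13) and ARO9 (−4.01 ± 0.10), which act in aromatic amino acid breakdown, and the phosphate transporter gene PHO84 (−4.81 ± 0.09, from 303 to 10.8 CPM). AZR1, OPT2 and DIP5, which encode membrane transporters, stood at −5.21, −5.07 and −4.45. FUS1 and BAR1, of the mating response, stood at −4.27 and −3.92, and ARG1, of arginine synthesis, at −3.46.

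In total 4173 of 6146 genes passed edgeR's quasi-likelihood test at an adjusted p under 0.05 after Benjamini-Hochberg adjustment, 1849 higher and 2324 lower in the deletion. Of these, 778 were at least 2-fold higher and 295 at least 2-fold lower. With upper-quartile factors the median of all genes moved from −0.08 to −0.15, and the higher share of the calls went from 44.3% to 37.9%, but with DESeq2 size factors they were −0.015 and 49.9%, so the excess of lower calls depends on the scaling. With a fixed biological coefficient of variation (BCV) of 0.2, above the fitted 5.54% and chosen after seeing the data, 1491 genes passed.

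Genes of the cell surface were prominent among the rises. Of 24 seripauperins 23 rose, with a median change of 7.63. All 7 DAN and TIR genes, for mannoproteins of the anaerobic cell wall, rose (median 5.76), among them DAN1 by 7.94 ± 0.12 and TIR1 by 7.47 ± 0.12. All 5 flocculin genes, for cell adhesion proteins, rose (median 3.75), from FLO5 at 2.16 and FLO10 at 2.90 to FLO1 at 3.75, FLO11 at 4.02 and FLO9 at 4.45. Seripauperins and flocculins, like MAL, HXT, COS and paired ribosomal protein genes below, were treated by name as families with near-identical copies. The value of a single member is therefore taken as uncertain, though not every member need have such a copy. For these 3 lists camera gave an adjusted p of 1.98e-15, 5.27e-06 and 1.10e-04, and adjusted p = 0.287, 0.301 and 0.287 with an estimated correlation. Among 14 other wall mannoprotein genes 9 rose, such as CWP1 by 4.58, and 2 fell, CCW12 and PIR1 (camera's adjusted p = 0.475 with an estimated correlation).

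Genes for carbon sources other than glucose also stood higher. Of 18 hexose transporter and sensor genes 16 rose (median 3.73), HXT16 by 8.92 ± 0.14 and HXT15 by 8.82 ± 0.14. Of 19 genes for maltose, sucrose and galactose use 17 rose (median 2.75), the maltase genes MAL12 and MAL32 by 7.86 and 7.64, while GAL1 of galactose use stood at −0.15 ± 0.15. Of 14 regulators of glucose repression 10 rose (median 1.41), the repressor gene NRG1 by 5.01 and MTH1 by 4.67. For these 3 lists camera's adjusted p = 0.242 with an estimated correlation. Of 17 genes of gluconeogenesis, the glyoxylate cycle and C2 use 14 rose and 2 fell (median 1.62), with PCK1, for the first enzyme of gluconeogenesis from oxaloacetate, at 4.06 ± 0.11 and ADH2 at −0.59. Of 15 TCA cycle genes 11 rose, of 31 nuclear respiratory chain genes 28 rose and 1 fell, and of 9 beta-oxidation genes 5 rose and 1 fell. These 4 lists had camera's adjusted p = 0.242 to 0.386 with an estimated correlation. The hexose kinase genes HXK1 and GLK1 rose by 4.44 ± 0.10 and 3.69 ± 0.09 in a list of 7 with 5 rises (camera's adjusted p = 0.324 with an estimated correlation).

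Stress and reserve genes rose as well. All 14 genes of trehalose and glycogen metabolism rose (median 2.57), as did all 10 salt and osmotic genes (median 3.28) and all 11 hypoxic genes (median 2.55), including ANB1 by 6.18. These 3 lists had camera's adjusted p = 0.242 with an estimated correlation. Of 11 genes induced in the environmental stress response 10 rose (median 2.10), the small heat shock gene HSP26 by 7.72 ± 0.12 and HSP12 by 6.24 ± 0.11. Of 8 DNA damage inducible genes 7 rose, the ribonucleotide reductase genes RNR3 by 6.47 ± 0.10, RNR2 by 3.81 and RNR4 by 3.27, and RNR1 stood at 0.15 ± 0.08. Of 15 iron uptake genes 11 rose and 3 fell, FRE4 by 6.07 and FRE1 at −1.06. All 8 vacuolar protease genes rose (median 0.95), PRB1 by 4.12 and PEP4 by 1.59. These 4 lists had camera's adjusted p = 0.287 to 0.347 with an estimated correlation. In 3 further lists rises prevailed, meiosis and sporulation (9 of 15, 2 fell), autophagy (6 of 9, 1 fell) and COS genes (8 of 11, 1 fell), with camera's adjusted p = 0.305 to 0.551 with an estimated correlation.

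Growth and mating genes stood lower. Of 137 ribosomal protein genes 134 fell and none rose (median −0.72), RPS28B at −1.14 and RPS22A at −1.10. All 23 ribosome biogenesis genes fell (median −0.55), BRX1 at −0.99 and NOG2 at −0.83. The 2 lists had camera's adjusted p = 5.36e-18 and 5.27e-06, and adjusted p = 0.305 and 0.242 with an estimated correlation. Of 7 a-specific genes, which give cells of mating type a their identity, 6 fell (median −1.03), BAR1 at −3.92 and the pheromone receptor gene STE2 at −2.42. Of 9 haploid-specific genes 6 fell and 1 rose, HO at −2.71 and FAR1 at −2.09. Of 7 phosphate genes 6 fell and only PHO89, for a sodium-coupled transporter, rose, by 7.26 ± 0.11. These 3 lists had camera's adjusted p = 0.301 to 0.475 with an estimated correlation.

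The glycan lists, closest to the title of the series, held few large changes in glucose. Of 15 protein O-mannosylation genes 3 rose, PMT3 the most at 0.99 ± 0.08, and 6 fell, MNT3 at −0.46 and PMT4 at −0.41 (median −0.06, and 0.00 with DESeq2 size factors). Of 14 N-glycan outer-chain genes 3 rose and 8 fell (median −0.29, mean 0.03), MNN4 by 2.01 and MNN10 at −0.61. Among 5 genes for mannosidases and free-glycan processing the vacuolar mannosidase gene AMS1 rose by 3.31 ± 0.09, MNS1 rose and MNL1 fell (median −0.06, mean 0.65). ER folding genes rose in 8 of 12, with the chaperone gene KAR2 at 1.20 and PDI1 at 1.32 (camera's adjusted p = 0.386 with an estimated correlation). The first 3 of these lists did not pass camera, with an adjusted p of 0.640, 0.501 and 0.552, and adjusted p = 0.648 to 0.680 with an estimated correlation. Nor did 6 others, given as rises and falls: wall glucanases (7 and 5 of 14), secretory proteases (3 and 3 of 8), ER-associated degradation (4 and 1 of 13, but 1 and 3 with upper-quartile factors), glycolysis (10 and 3 of 16), alpha-specific genes (0 and 2 of 3) and mitochondrially encoded genes (3 and 2 of 7). Camera ranked the mannosidase and mitochondrial lists higher although their medians were −0.06 and −0.03, and the N-glycan list lower although its mean was positive. For the 6 lists the adjusted p by camera was 0.0526 to 0.672, and adjusted p = 0.364 to 0.824 with an estimated correlation.

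Of 37 lists, camera called 28 in glucose (23 higher, 5 lower), and none with an estimated correlation in this or the other 4 comparisons. That form of camera takes its degrees of freedom from the 2 residual ones of the fit, so few lists could pass it. For the glucose repression regulators the estimated correlation was −0.062, below the preset 0.01, yet camera's unadjusted p went from 4.93e-05 to 0.0497. A lack of calls in that form is therefore not evidence that correlation between genes accounts for the list results. At an unadjusted p under 0.05 with an estimated correlation camera had 7, 3, 2, 5 and 0 lists over the 5 comparisons, and fry at its adjusted p had 32, 13, 31, 34 and 30. Adjusted over the list alone, the counts were those above except 12 rises among TCA cycle genes and 1 fall among the glucose repression regulators.

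**Figure D2:**
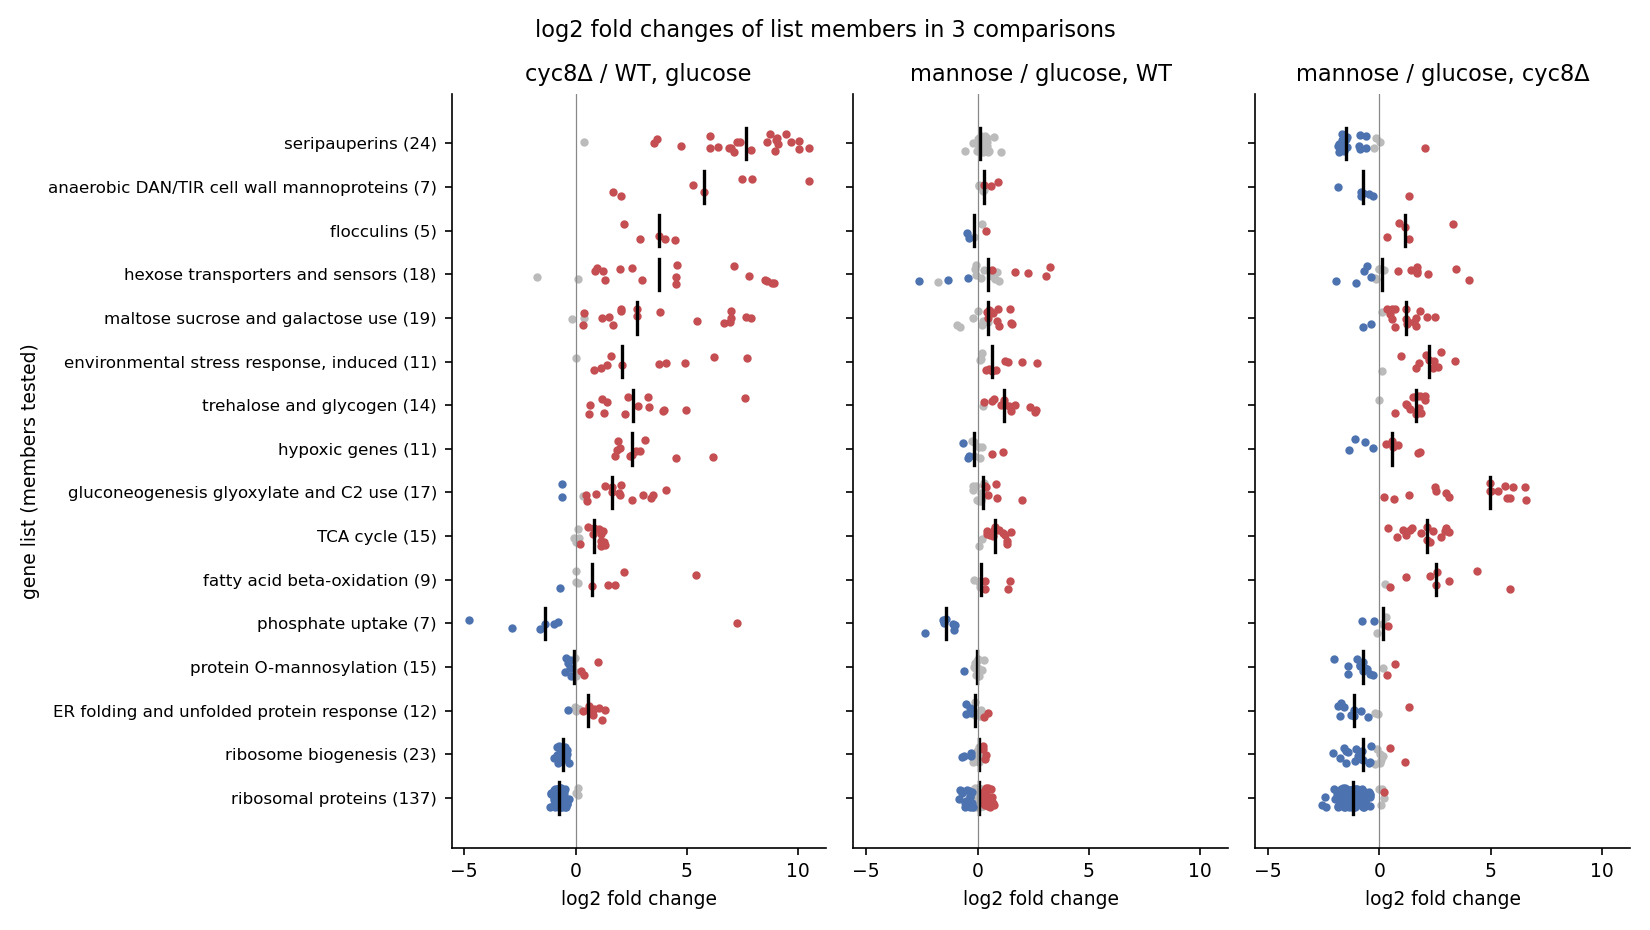
log2 fold changes (x axis) of the members of 16 gene lists (y axis, number of tested members in parentheses) in 3 comparisons. Points are genes, red where higher and blue where lower at an adjusted p under 0.05 by edgeR, grey otherwise, and black bars are medians, such as 7.63 for seripauperins in the first panel and 4.97 for gluconeogenesis in the third.

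The second comparison asks what 3 h in mannose did in wild type, 1 library against 2. The largest rise among the named genes was in the high-affinity hexose transporter gene HXT7, which went from 108 ± 2.78 CPM (SD, n = 2) to 1033 CPM, a rise of 3.25 ± 0.10. Its near-identical copy HXT6 rose by 3.06 ± 0.10, while the low-affinity transporter gene HXT1 fell (−2.65 ± 0.11). HXK1 rose by 2.84 ± 0.10 (adjusted p = 4.41e-43, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), the stress gene HSP12 by 2.68 ± 0.11 and MTH1, a regulator of glucose sensing, by 2.59 ± 0.11. The largest falls were in transcripts of the mitochondrial genome, ATP6 at −5.01 ± 0.23 and COB at −3.02 ± 0.12. The intron reading frames BI2, BI3 and BI4, which overlap COB, stood at −4.56, −4.66 and −2.83.

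In wild type 2300 genes passed edgeR's quasi-likelihood test at an adjusted p under 0.05 after Benjamini-Hochberg adjustment, 1263 higher and 1037 lower in mannose. At least 2-fold were 133 higher and 116 lower. The count rests in part on the glucose pair: it was 1516 without wild-type glucose replicate 1, 1520 without replicate 2, and 1829 once trends on GC content and coding length were removed. With a fixed BCV of 0.2 it was 149. The last 2 alternatives were chosen after seeing the data. Of the 1829 genes without the trends, taken from nuclear reading frames of the reference only, 1454 were among the 2300 main calls. Changes in mannose followed GC content, with a median of −0.78 over 98 nuclear reading frames of up to 34% GC and 0.30 over 447 above 46% (Spearman's rho across genes 0.422). Between the wild-type glucose replicates (2 over 1) the smallest and largest medians of any GC bin were −0.12 and 0.08, relative to the median of all the genes binned. Spearman's rho across genes was 0.236 there, so a rank trend on GC content was present without a change of medium.

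Reserve and respiratory genes rose in mannose in wild type. Of 14 trehalose and glycogen genes 13 rose (median 1.21, and 1.17 without the GC and length trends), GAC1 by 2.62 ± 0.18 and GPH1 by 2.56 ± 0.11. Of 31 nuclear respiratory chain genes 24 rose (median 0.67, then 0.68), CYT1 by 1.36. The 2 lists had camera's adjusted p = 3.32e-09 and 2.13e-08, and adjusted p = 0.434 with an estimated correlation. Of 15 TCA cycle genes 13 rose (median 0.77, then 0.70), SDH1 by 1.51, and of 19 sugar-use genes 12 rose (median 0.49, then 0.42), MAL12 by 1.53. Further rises were in 8 of 11 stress-response genes, 5 of 7 genes for hexose kinases and GDP-mannose supply, 6 of 8 vacuolar protease genes, 6 of 10 salt genes, 9 of 14 other wall mannoprotein genes (1 fell) and 8 of 11 COS genes. Without the GC and length trends 3 salt genes rose, and of the other wall mannoprotein genes 6 rose and 3 fell. These 8 lists had camera's adjusted p = 0.598 to 0.651 with an estimated correlation. In GDP-mannose supply PMI40 rose by 0.48 ± 0.09 and SEC53 by 0.37 ± 0.09. All 7 phosphate genes fell (median −1.41, then −1.49), SPL2 at −2.35, PHO84 at −1.41 and PHO5 at −1.07, with camera's adjusted p = 0.434 with an estimated correlation. Of 7 mitochondrially encoded genes 6 fell (median −1.53), and COX2 stood at −0.24 ± 0.11, with −0.016 without wild-type glucose replicate 1 and −0.43, called, without replicate 2. Of 7 a-specific genes 4 fell and 1 rose. These 2 lists had camera's adjusted p = 0.606 with an estimated correlation. Mitochondrial reading frames took 0.627% and 0.557% of the counts in wild type in glucose and 0.251% in mannose, and their GC content of 10.4% to 33.3% lies at the low end of the trend above.

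The glycan lists again showed few calls in wild type. Of 15 O-mannosylation genes only PMT7 changed (−0.61 ± 0.12), of 14 N-glycan genes 3 rose, among them MNN4 by 1.00, and of 5 mannosidase genes AMS1 rose, by 0.89 ± 0.11. None of the 24 seripauperins was called by edgeR, also at an unadjusted p under 0.05, or by DESeq2 (median 0.13), and of 137 ribosomal protein genes 35 rose and 17 fell (18 and 15 without the GC and length trends). Of 12 ER folding genes 2 rose and 5 fell, and of 13 genes for ER-associated degradation 2 fell. Of 17 gluconeogenesis genes 6 rose (4 without the trends), ALD4 the most at 1.99. These 8 lists had an adjusted p of 0.0561 to 0.701 by camera, and adjusted p = 0.651 to 0.891 with an estimated correlation. Also without a call by camera were 12 lists with a few members that passed, as rises and falls: DAN and TIR genes (3 and 0), flocculins (1 and 2), glucose repression regulators (5 and 3), glycolysis (1 and 0, but 1 and 9 without the GC and length trends), wall glucanases (3 and 5), secretory proteases (1 and 1), autophagy (1 and 1), hypoxic genes (2 and 3), DNA damage (4 and 2, then 2 and 2), iron uptake (4 and 3, then 1 and 4), beta-oxidation (4 and 0) and ribosome biogenesis (4 and 4, then 2 and 3). Among these camera's direction was lower where the mean (hypoxic 0.01, iron 0.01) or the median (ribosome biogenesis 0.05) was positive, and adjusted p = 0.651 to 0.942 with an estimated correlation. Camera called 13 of 37 lists (10 higher, 3 lower). Adjusted over the list alone there were 14 rises each in the trehalose and TCA lists, 9 in the stress list, 7 falls in the mitochondrial list, 4 rises and 6 falls among wall glucanases, and 6 rises and 3 falls among 18 hexose transporter genes against 5 and 3 over all genes. For that list camera gave an adjusted p of 0.124, and adjusted p = 0.651 with an estimated correlation.

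The third comparison asks what mannose did in the deletion, again 1 library against 2. Genes for growth on non-sugar carbon rose the most. PCK1 went from 109.6 ± 19.8 CPM (SD, n = 2) to 10509 CPM, a rise of 6.58 ± 0.12 (adjusted p = 4.85e-68, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The acetate transporter gene ADY2 rose by 6.51 ± 0.11, IDP2, for an isocitrate dehydrogenase, by 6.02 ± 0.10, CTA1, for peroxisomal catalase, by 5.86 ± 0.12 and MLS1, for malate synthase, by 5.84 ± 0.11. The largest falls were in short reading frames: the proton pump regulators PMP2 (−5.03 ± 0.32) and PMP1 (−3.00 ± 0.15), LSM2 of RNA processing (−3.41 ± 0.20), OST2 of the oligosaccharyltransferase (−3.20 ± 0.21) and ERV14 of vesicle transport (−3.13 ± 0.23). Without the GC and length trends PMP2 stood at −3.99, LSM2 at −2.35, OST2 at −2.22, ERV14 at −2.25 and PMP1 at −1.82.

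In the deletion 4746 genes passed edgeR's quasi-likelihood test at an adjusted p under 0.05 after Benjamini-Hochberg adjustment, 2308 higher and 2438 lower in mannose, of which 1148 and 914 by at least 2-fold. With upper-quartile factors the median of all genes moved from −0.04 to −0.30 and the higher share of the calls from 48.6% to 37.4%, and with DESeq2 size factors they were −0.025 and 49.2%. With a fixed BCV of 0.2, 2496 genes passed. Medians by GC content ran from −0.94 in the lowest bin to 0.56 in the highest. Between the deletion's glucose replicates (2 over 1) the smallest and largest medians of any bin were −0.05 and 0.03. These are relative to the median of all the genes binned, and Spearman's rho across genes was −0.113, in the other direction. The library stood apart in other measures too, with 26195734 counts and 2.65% of them in mitochondrial reading frames, against 0.744% and 0.857% in glucose.

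All 17 genes of gluconeogenesis, the glyoxylate cycle and C2 use rose (median 4.97, 4.71 with upper-quartile factors and 4.11 without the GC and length trends). Of 15 TCA cycle genes all rose (median 2.13), KGD1 by 3.13 ± 0.10 and SDH1 by 3.01. Of 31 nuclear respiratory chain genes 26 rose and 3 fell, COX13 by 2.81 and ATP20 at −1.42 (−0.46 without the trends), and of 9 beta-oxidation genes 8 rose, FOX2 by 4.38. Of 7 mitochondrially encoded genes 6 rose and OLI1 fell (−0.22, but −0.12 and not called without deletion glucose replicate 2, and −0.43 without replicate 1) with a median of 1.62. COX1 rose by 1.78 ± 0.10, COB by 0.86 ± 0.09 and ATP6 by 1.33 ± 0.15, the last at 2.03 without deletion glucose replicate 1 and 0.75 without replicate 2. For these 5 lists camera's adjusted p was at most 0.0466, and adjusted p = 0.499 to 0.584 with an estimated correlation. Of 11 stress-response genes 10 rose, HSP42 by 3.38, of 14 trehalose and glycogen genes 13, GLC3 by 2.03, of 10 salt genes 9, SIP18 by 4.61, and of 8 vacuolar protease genes 7, PRC1 by 1.01 (0.23 without the trends). Of 19 sugar-use genes 16 rose and 2 fell, MAL11 by 2.48 and SUC2 at −0.37. Without the GC and length trends the medians of the last 2 lists went from 0.62 to 0.16 and from 1.19 to 0.71, with 4 rises and 2 falls among vacuolar proteases, and 6 salt genes rose. These 5 lists had camera's adjusted p = 0.499 to 0.550 with an estimated correlation. All 5 flocculin genes rose (median 1.14), FLO11 by 3.29 ± 0.09, but without the GC and length trends the median was 0.02 with 1 rise, FLO11 at 1.92, and 2 falls (camera's adjusted p = 0.499 with an estimated correlation).

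Genes of translation, O-mannosylation, ER folding and the seripauperins fell in mannose in the deletion. Of 137 ribosomal protein genes 132 fell (median −1.20), RPL39 at −2.60, and only RPL4A rose, by 0.22 ± 0.10, which was −0.0371 with upper-quartile factors, −0.48 without the trends and 0.12, not called, without deletion glucose replicate 2. Of 23 ribosome biogenesis genes 15 fell and 2 rose, UTP22 at −2.09 and NOP2 by 1.16. Of 15 O-mannosylation genes 12 fell and 2 rose (median −0.74, −0.79 without the GC and length trends), PMT7 at −2.03 ± 0.15, PMT5 at −1.41 ± 0.12 and KRE2 by 0.68 ± 0.09. Of 12 ER folding genes 9 fell, the chaperone gene LHS1 at −1.88 and the oxidase gene ERO1 at −1.79, and only HAC1, for the transcription factor of the unfolded protein response, rose, by 1.31 ± 0.10. Of 24 seripauperins 20 fell and 1 rose, PAU24 at −1.88 and PAU23 by 2.05. These 5 lists had camera's adjusted p = 2.50e-18 to 0.0278, and adjusted p = 0.499 to 0.583 with an estimated correlation.

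The vacuolar mannosidase gene AMS1 went from 128 ± 11.5 CPM (SD, n = 2) to 1025 CPM in mannose in the deletion, a rise of 3.00 ± 0.09, the largest in its list of 5, in which MNL1, MNL2 and MNS1 fell (median −0.45, mean 0.34). The GDP-mannose supply genes fell, PMI40 at −0.96 ± 0.10, SEC53 at −1.45 ± 0.10 and PSA1 at −1.28 ± 0.11, while GLK1 and HXK1 stood at 0.81 and 0.72, but at −0.19 and 0.30 without the GC and length trends. Of 14 N-glycan genes 3 rose and 6 fell, and of 14 wall glucanase genes 5 rose and 9 fell, UTR2 at −2.16 and GAS1 at −1.90. None of these 4 lists passed camera (adjusted p of 0.173 to 0.874, and adjusted p = 0.700 to 0.892 with an estimated correlation). Hexose transporter genes went both ways, 8 up and 5 down of 18, HXT5 by 3.43 and HXT4 at −1.97, with a median of 0.10 that was −0.16 with upper-quartile factors and −0.45 without the GC and length trends, with 9 falls (camera's adjusted p = 0.752 with an estimated correlation). Lists without a call by camera also held falls in 10 of 15 iron uptake genes, 7 of 9 haploid-specific genes, 6 of 7 DAN and TIR genes and 5 of 8 DNA damage genes, and rises in 9 of 14 glucose repression regulators (2 fell, 5 without the trends), 7 of 9 autophagy genes and 7 of 15 meiosis genes. Their adjusted p = 0.499 to 0.752 with an estimated correlation. The medians of glycolysis, ER-associated degradation, phosphate and COS genes were 0.09, 0.12, 0.14 and 0.07 and turned to −0.16, −0.14, −0.11 and −0.18 with upper-quartile factors (camera's adjusted p = 0.892 to 0.984 with an estimated correlation). Without the GC and length trends they were −0.53, 0.07, −0.24 and 0.23, with 1 rise and 12 falls of 16 in glycolysis and 0 rises and 4 falls of 7 in phosphate. Camera called 16 of 37 lists (11 higher, 5 lower). Adjusted over the list alone, the counts given for this comparison were the same except 4 falls among the respiratory chain genes.

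**Figure D3:**
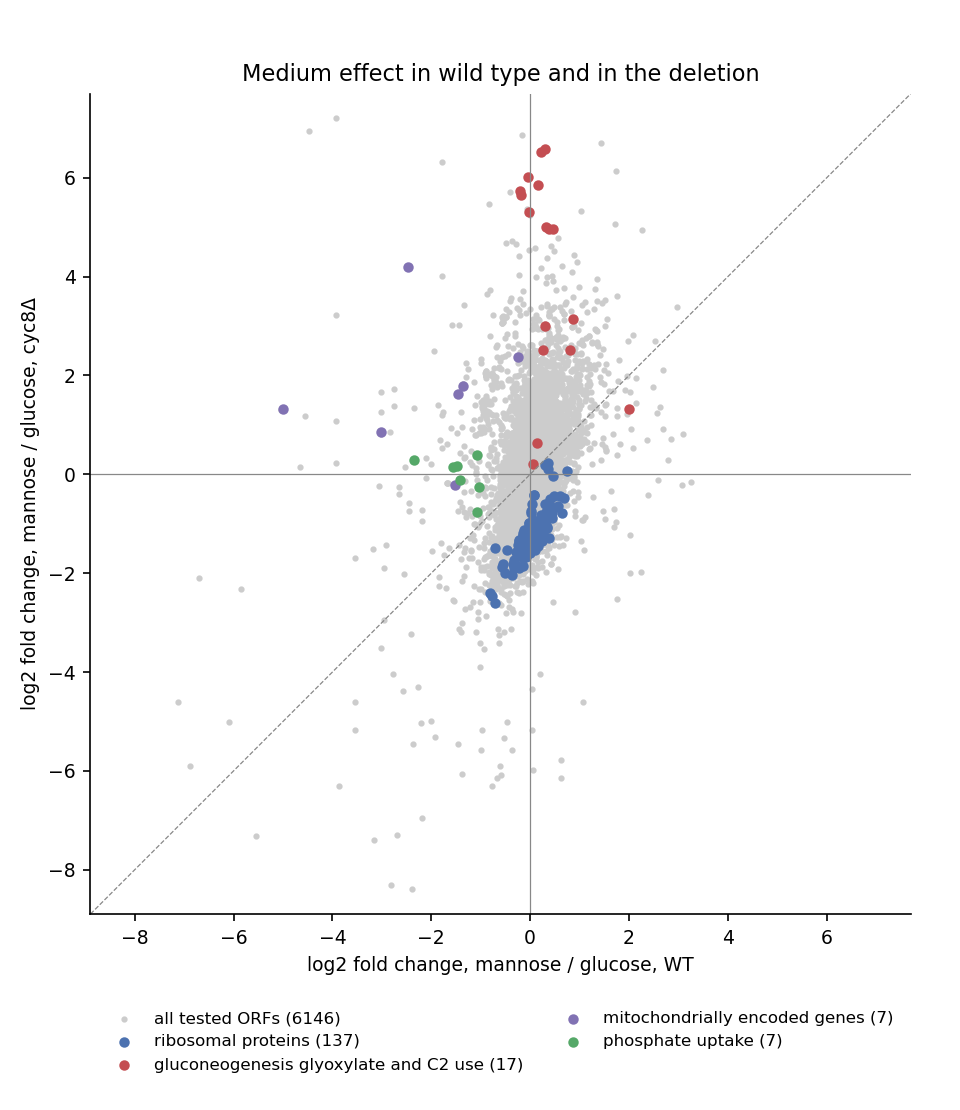
log2 fold changes between mannose and glucose in wild type (x axis) and in the deletion (y axis) for 6146 open reading frames, with 4 gene lists in colour and the line of equal change dashed. Gluconeogenesis genes have a median of 0.26 on the x axis and 4.97 on the y axis, and ribosomal protein genes 0.06 and −1.20.

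The fourth comparison sets the deletion against wild type in mannose, 1 library against 1. The folds are therefore the result, and any call rests on the spread of the glucose pairs. HXT13, a hexose transporter gene with near-identical copies, differed the most, at 0.544 CPM in wild type and 795 CPM in the deletion, a change of 10.51 ± 0.19. PCK1 differed by 10.34 ± 0.19, SPG4, a gene of stationary phase, by 9.88 ± 0.20, HXT15 by 9.70 and HXT16 by 9.63. Lower in the deletion besides CYC8 were AZR1 (−7.17 ± 0.32), the metal reductase gene FRE7 (−4.68 ± 0.17), HO, for mating type switching (−4.21 ± 0.16), and PHO84 (−3.51 ± 0.13). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 4879 genes passed, 2352 higher and 2527 lower in the deletion, of which 1454 and 1278 by at least 2-fold. With upper-quartile factors the median of all genes moved from −0.07 to −0.39 and the higher share from 48.2% to 37.1%, and with DESeq2 size factors they were −0.011 and 50.2%. With a fixed BCV of 0.2, 2820 genes passed.

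Many lists that stood higher in the deletion in glucose did so in mannose. All 24 seripauperins, 5 flocculins, 18 hexose transporter genes, 19 sugar-use genes, 11 hypoxic genes, 10 salt genes, 11 stress genes and 14 trehalose and glycogen genes were called higher, with medians of 6.14, 5.48, 2.97, 2.76, 3.36, 3.36, 3.64 and 2.63, that of the flocculins going to 4.28 without the GC and length trends. The median of each of these 8 lists exceeded those of all 10000 random lists of genes of matching expression, and adjusted p = 0.306 to 0.366 by camera with an estimated correlation. Of 17 gluconeogenesis genes 16 stood higher (median 5.73), and all 7 mitochondrially encoded genes did (median 3.79), with camera's adjusted p = 0.330 and 0.356 with an estimated correlation. All 137 ribosomal protein genes were called lower (median −1.99), as were 22 of 23 ribosome biogenesis genes (median −1.32), each below all 10000 random lists. Of 15 O-mannosylation genes 11 were lower and 1 higher, and the median of −0.77 lay at percentile 4.70 of random lists. These 3 lists had camera's adjusted p = 0.306 to 0.330 with an estimated correlation. AMS1 stood at 23.9 CPM in wild type and 1025 CPM in the deletion (5.42 ± 0.13). Camera called 24 of 37 lists (19 higher, 5 lower).

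The fifth comparison asks whether the medium effect differed between the genotypes, by the interaction term, in which positive values mean a change in mannose that is higher in the deletion than in wild type. PCK1 had an interaction of 6.28 ± 0.19 (adjusted p = 1.12e-47, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), ADY2 of 6.30 ± 0.33 and SPG4 of 6.29 ± 0.40. The mitochondrial genes VAR1 and ATP6 had 6.65 ± 0.59 and 6.34 ± 0.27. Each fell in mannose in wild type and rose in the deletion. VAR1 was scarce, at 0.735 and 0.129 CPM in wild type in glucose and mannose and 0.714 CPM in the deletion in glucose. Its rise rests on 12.7 CPM in the deletion in mannose. ATP6 stood at 28.2 ± 16.7 CPM (SD, n = 2) in the deletion in glucose. Its rise there was 2.03 without deletion glucose replicate 1 and 0.75 without replicate 2. Negative interactions were led by hexose transporter genes, HXT4 at −4.22 ± 0.16, HXT7 at −3.41 ± 0.15 and HXT6 at −3.27 ± 0.15. HXT7 stood at 2530 CPM in the deletion in glucose and 2271 CPM in mannose. PMP2 and SSU72, of transcription termination, had −2.82 ± 0.45 and −2.74 ± 0.34. The test called 3943 genes, 1826 positive and 2117 negative, of which 892 and 768 by at least 1 log2 unit. With upper-quartile factors the median of all genes moved from −0.08 to −0.32 and the positive share of the calls from 46.3% to 33.0%, and with DESeq2 size factors they were −0.08 and 46.1%. With a fixed BCV of 0.2, 818 genes passed.

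Of 17 gluconeogenesis genes 15 had positive interactions and 1 a negative one (median 4.58), and of 15 TCA cycle genes 12 were positive (median 1.06). Of 9 beta-oxidation genes 8, of 31 respiratory chain genes 21, of 19 sugar-use genes 10 and of 11 stress genes 7 were positive, with 6, 4 and 1 negative in the last 3 (respiratory chain 1 without the GC and length trends). All 7 mitochondrially encoded, 7 phosphate and 5 flocculin genes were positive (medians 3.13, 1.47 and 1.34, the last 0.49 with 3 positive without the trends). These 9 lists had camera's adjusted p = 0.472 to 0.638 with an estimated correlation. Negative were 134 of 137 ribosomal protein genes (median −1.27), 16 of 23 ribosome biogenesis genes (1 positive), 18 of 24 seripauperins (1 positive), 10 of 12 ER folding genes (1 positive) and 11 of 15 O-mannosylation genes (2 positive, median −0.72). In the list of hexose kinases and GDP-mannose supply 6 of 7 were negative, HXK1 at −2.12, PMI40 at −1.44, SEC53 at −1.82 and PSA1 at −1.45. These 6 lists had camera's adjusted p = 0.472 to 0.524 with an estimated correlation. AMS1 had an interaction of 2.11 ± 0.14. Camera called 15 of 37 lists (9 positive, 6 negative), and adjusted over the list alone ER folding had 11 negative members.

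Genes called in both the deletion in glucose and in mannose in wild type numbered 688 higher in both and 615 lower in both, against 380 and 392 for independent lists. The 2 comparisons share both wild-type glucose libraries, which cannot be split further. Their fold changes correlated across genes at r = 0.342, and simulated unchanged groups against the same libraries gave r = 0.392, with a covariance of 0.0104 against 0.219. Over 20 fits of such simulated groups at most 0 genes were called in both comparisons. HXT7, HXK1, GLK1, HSP12, GAC1 and GPH1 were among the genes higher in both. Comparisons without a shared library also overlapped. The deletion in glucose and in mannose had 1459 genes higher in both and 1721 lower in both (r = 0.781 across genes), against 708 and 956 for independent lists. Mannose in wild type and in the deletion had 831 and 678 (r = 0.368), against 474 and 411. Both medium effects followed GC content (Spearman's rho across genes 0.422 and 0.287). The genotype effects did so less strongly (0.147 in glucose and 0.217 in mannose). None of these overlaps was computed without the trend on GC content, so how much of each the trend accounts for cannot be told.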

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

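Chosen only after their results were seen were the tests of wild-type RNA, of one lower yield of mitochondrial RNA, and the paired form of the intervals for the gluconeogenesis list. In 3943 genes (818 with a fixed biological coefficient of variation of 0.2) the effect of the medium differed between the genotypes by the interaction term of edgeR's quasi-likelihood test, which is why the following are listed. The named genes with the largest positive interactions were VAR1 (6.65), ATP6 (6.34), ADY2 (6.30), SPG4 (6.29) and PCK1 (6.28). Those with the largest negative interactions were HXT4 (−4.22), HXT7 (−3.41), HXT6 (−3.27), PMP2 (−2.82) and SSU72 (−2.74). VAR1 stood at 12.7 CPM in the deletion in mannose and only 0.129 to 0.735 CPM in the other groups. ATP6 differed between the deletion glucose replicates (28.2 ± 16.7 CPM, SD, n = 2). Lists that camera called had median interactions of 4.58 (gluconeogenesis, glyoxylate cycle and C2 use), 1.06 (TCA cycle), 0.54 (nuclear respiratory chain), 3.13 (mitochondrially encoded), 0.80 (maltose, sucrose and galactose use), 1.34 (flocculins), 1.47 (phosphate), 1.13 (stress response) and 1.21 (beta-oxidation), and of −1.44 (hexose kinases and GDP-mannose supply), −0.72 (O-mannosylation), −0.98 (ER folding), −1.62 (seripauperins), −1.27 (ribosomal proteins) and −0.73 (ribosome biogenesis). These 15 lists had adjusted p = 0.472 to 0.638 with an estimated correlation.

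The 17 genes of gluconeogenesis, the glyoxylate cycle and C2 use had a median interaction of 4.58, with PCK1 at 6.28 ± 0.19. With upper-quartile scaling the median was 4.34 (95% bootstrap interval 2.00 to 5.61), above the bound of 1 set for a scaling effect. Scaling factors move all genes of a library alike. The median of all genes went from −0.08 to −0.32, so this choice of factors could hardly bring the list below 1. The intervals resample the genes of the list and not libraries, so they leave out variation between cultures. Without trends on GC content and coding length 87.0% of it was left (72.6 to 99.2), which argues against these trends as the whole cause. With all libraries thinned to the smallest total 102% was left (97.46 to 104). Thinning keeps the expected folds, so this outcome was largely fixed in advance and does not decide on depth. The paired intervals of the share left replaced unpaired intervals of the medians, 1.93 to 5.81 and 2.19 to 5.96, which were too wide to exclude a loss of 50%. A different response to mannose in the deletion may underlie the pattern. It is a hypothesis found and tested on the same libraries, with 1 library per genotype in mannose. Whether those cultures differed in another way was not tested.

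The deletion libraries held 71, 124 and 180 CYC8 counts, 1.10% (95% interval 0.820 to 1.39), 1.48% (1.18 to 1.77) and 4.02% (3.29 to 4.66) of the level in the wild-type library where CYC8 was lowest. Wild-type RNA of either medium may be a source: with each gene set against its lowest wild-type library, 0 of 4474 genes of at least 10 CPM in each wild-type library lay below that share beyond counting error. Against wild type in the same medium it was 0 in the glucose libraries and 1 in the mannose library, AZR1 at 0.688% (upper limit 1.58, from 6 counts) against 4.02% (lower limit 3.38) for CYC8, which argues against wild-type RNA from mannose as the only source there but rests on 1 gene near the floor. Reads from other open reading frames may also be: 14 of them match CYC8 over at least 30 bases at 95% identity, over 141 of its bases between positions 45 and 1761. The files give no positions of reads, so the tables do not decide between them.

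Mitochondrially encoded transcripts fell in wild type in mannose (median −1.53, ATP6 at −5.01 ± 0.23). One lower yield of all mitochondrial RNA would move them alike, but their changes ranged over 4.77 log2 units, against a bound of 2.43 from the least precise member. A GC bias of the mannose library cannot be told apart. The 117 nuclear open reading frames of the lowest 2% in GC content had a median of −0.71 (−0.82 to −0.55), with an interval that spans the bound of −0.77. This interval resamples genes and not libraries. Mitochondrial open reading frames reach down to 10.4% GC, below any nuclear one of the trend, so some lie outside the range where the trend can be measured. A lower level of mitochondrial RNA in mannose in wild type remains open and was not tested.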

How the results depend on the processing

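The crossed replicate block, the fixed biological coefficient of variation (BCV) of 0.2, the merging of near-identical copies and the removal of GC content and coding length trends were chosen after the results were seen. Over 479 results for 285 genes, 7620 alternative values were computed. Of these 6870 kept direction and side of the threshold, 95 changed sign without a call in either setting, 559 kept direction but not the threshold, 68 newly passed it and 28 changed sign with a call in at least 1 of the settings. Of these 28 sign changes 21 came from the additive model, which forces 1 medium effect on both genotypes: in the deletion in glucose CIT2 0.84, ATP6 0.14, COX3 0.71 and CTA1 0.89, for mannose in wild type PDC5 −0.17, KEX2 −0.0322, ATG1 0.38, FLO9 0.25, FLO1 0.55, PIR3 0.45, FRE5 −0.17, COX1 0.52, PMI40 −0.18 and SEC53 −0.44, and for mannose in the deletion MAL33 0.45, SUC2 0.35, HXT4 0.68, TIR4 0.11, PHO5 −0.28, COB −0.61 and ATP6 −0.55. In mannose in the deletion 5 more came without the GC and length trends, ATP15 0.0235, GLK1 −0.19, FUS3 −0.0340, RPL4A −0.48 and RPL3 −0.31, and 1 with upper-quartile factors, RPL4A −0.0371. In the deletion in glucose IDH1, at −0.00389 and not called, ranged from −0.0777 to 0.18 with 1 library left out, the last without deletion glucose replicate 1. For these 7 the cause was not tested. The additive model called 2350 genes for genotype in glucose and 215 for mannose in either genotype. With a fixed BCV of 0.2, above the fitted 5.54%, 1491, 149, 2496, 2820 and 818 genes passed in the 5 comparisons (genotype in glucose, mannose in wild type, mannose in the deletion, genotype in mannose, interaction). A threshold of 1 on the log2 fold change left 1073, 249, 2062, 2732 and 1660 by construction. DESeq2 called 1529 genes for mannose in wild type, and the cause was not tested. Leaving out 1 library gave 3538 to 4179, 1516 to 2734, 4608 to 4765, 4766 to 5003 and 3538 to 4106. For mannose in wild type the count was 1516 without wild-type glucose replicate 1 and 1520 without replicate 2, where each arm is 1 library assumed to vary like the other groups, and 2734 and 2715 without deletion glucose replicates 1 and 2. With an estimated correlation camera called 0, 0, 0, 0 and 0 lists (7, 3, 2, 5 and 0 at an unadjusted p under 0.05), and fry 31 for mannose in the deletion and 30 for the interaction. With replicate number as a block 3978 genes passed for genotype in glucose, with the numbers crossed 4287 and with the glucose libraries alone 4079. Deviations of libraries with the same number correlated across genes at r = −0.0463 over 6146 genes and −0.274 over 2931 genes of at least 32 CPM, which gives no sign of pairs by number and leaves open whether libraries were paired in another way. Without the GC and length trends 3948, 1829, 4521, 4597 and 3794 genes passed. Of these 3726, 1454, 3968, 4161 and 3344 were among the main calls. Over all genes 1, 1, 79, 34 and 15 of these shared calls changed sign. With copies merged 3915, 2185, 4573, 4679 and 3799 genes passed. The planned pseudocount and value filter for normalized values were not run, since counts were deposited. Depth limits the smallest values: HXT14 and PAU16 had 1 to 2 counts in some libraries, and no folds are given for them.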

Other observations

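The tests of a smaller version of the deletion profile, with the ratios of single lists, were chosen only after their results were seen. In the deletion in glucose DIT1, for the first step of dityrosine synthesis in the spore wall, rose by 6.52 ± 0.11 (from 1.91 to 175 CPM, n = 2 each) and SPS100, also of the spore wall, by 4.56 ± 0.17, while SPS4 fell (−1.03 ± 0.17). The secreted aspartyl protease genes YPS3 and YPS6 rose by 4.04 ± 0.08 and 3.66 ± 0.10, and KEX2 of the same list fell (−0.36 ± 0.08). Of the wall enzymes SCW10 and CRH1 rose by 1.87 ± 0.08 and 1.20 ± 0.08, and DSE4 and SCW11, which act in daughter cell separation, fell (−1.53 ± 0.07 and −1.48 ± 0.08). The selective autophagy receptor genes ATG34 and ATG19 rose by 2.27 ± 0.12 and 1.20 ± 0.08.

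Open reading frames near chromosome ends were tested for an excess of rises in the deletion in glucose. Within 25 kb of an end 76 of 216 (35.2%) rose at least 2-fold, counting each near-identical family once, against 609 of 5392 (11.3%) elsewhere (Fisher's exact test, p = 2.95e-19). Without seripauperins and genes with copies it was 60 of 186 (32.3%) against 602 of 5341 (11.3%, Fisher's exact test, p = 7.97e-14). Falls of at least 2-fold, with all copies counted, were 16 of 303 (5.28%) near an end and 208 of 5525 (3.76%) elsewhere (Fisher's exact test, p = 0.169). The tests take neighbouring reading frames as independent. Position near an end is a candidate explanation for part of the rises, among them PAU24 (10.48 ± 0.14), and the test does not separate position from the kinds of genes that lie there.

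Sugar-use and reserve-carbohydrate genes rose both with mannose in wild type and with the deletion in glucose, among them GPH1 (2.56 and 4.96) and HXK1 (2.84 and 4.44). If mannose gave a smaller version of the whole deletion profile, other lists should have moved in proportion. For trehalose and glycogen genes the median in mannose was 0.470 of that in the deletion, and a bound of 0.235 was set from this list. For 43 genes of the seripauperin, hypoxic and DNA damage lists the ratio was 0.02 (upper 95% limit 0.0384). The limits here resample genes and not libraries. The limit of the 43 genes holds the median in the deletion fixed, while the intervals of the single lists below resample both medians. It also treats the 24 seripauperins as independent, though near-identical copies seem to share reads, so it may be too narrow. The sugar-use list itself had 0.178 (0.0694 to 0.333) and the hexose transporters 0.124 (−0.0569 to 0.278). Both ratios lie under the bound of 0.235 too, with intervals that span it, so the bound alone does not set these lists apart from the 43 genes. Both lists moved less in proportion than the reserve genes, and the interval of the transporters includes the value of the 43 genes. Mannose in wild type may share only a part of the deletion profile, clearest for the reserve genes, a hypothesis that rests on 1 mannose library and on shared wild-type controls.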
